A study of Hordeum vulgare with 2 samples.

How the data were processed

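Degradome sequencing reads the 5′ ends of uncapped RNA fragments, so a position where a microRNA guides cleavage of its target stands out as a pile of reads that start at the same nucleotide. Shoots of barley seedlings were sampled from the cultivars ZD9 and XZ153, with 1 library each. Per the labels' protocols, the seedlings were grown hydroponically at potassium levels of 0.01 mM or 1 mM, but which level, or which mixture of levels, each library came from is not stated in the labels. Per the labels' protocols, poly(A) RNA from 20 µg of total RNA was ligated to a 5′ adapter, reverse transcribed, amplified over 15 PCR cycles, selected for inserts of 200 to 400 bp and read as single 50 nt reads.

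Each library has 1 deposited table of CleaveLand output, a program that aligns small RNAs to transcripts and looks up the degradome reads at the predicted cut. The version, the aligner, the transcript release and the genome build are not given in the sources used here. Each record gives 1 small RNA, 1 transcript and 1 position. Per the file headers, the raw read count is the number of reads at the site, and it was used for ZD9 only; no read column was used for XZ153. Per the file headers, a second ZD9 column holds normalised reads. The deposited normalised values are RPM in form, but 1 read was worth 28.6, which corresponds to a total of 34944 reads. The raw counts in the list sum to 34935, so the scale is the list and not the library, and the depth of both libraries is unknown. Per the file headers, the minimum free energy ratio compares the site with a perfectly paired one, and its lowest value was 0.65 in both lists. The Allen score in the deposited tables is a mismatch penalty in which lower means better paired. The deposited category runs from 0, the highest position of its transcript, to 4, a single read. All 10289 category 4 sites of ZD9 held 1 read and the lowest count in the other categories was 2. The deposited p-value of each record, computed by the authors with CleaveLand, is not adjusted for the number of records. It asks how often an alignment at least as good would meet a position of that category by chance within 1 library, and it compares no cultivars.

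The ZD9 list used here ends early. Its 15544 records with values are sorted by transcript ID and stop at HORVU2Hr1G036110.5, after which 1941 records carry a site and a small RNA but no values. A further 3 lines of ZD9 and 20 lines of XZ153 were left out and are not analysed here. Comparisons of records between libraries were therefore made over IDs up to that transcript, called the shared range, where XZ153 has 8350 of its 40424 records. Values of the whole XZ153 list are named as such. This restriction was chosen after the data were seen.

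A microRNA family is the number in the small RNA name, and a gene is the transcript ID without its isoform suffix. A record was called supported at category 0 to 2 with a p-value of at most 0.05, a combination chosen after the data were seen; the categories and the limit had each been listed before the data were examined. Isoforms of 1 gene repeat the same cut, so supported records were also counted as distinct pairs of family and gene. Their reads are not plain copies, since read counts and categories at 1 cut differed between isoforms. How reads were assigned to isoforms is not given in the sources used here. The deposited p-values were decomposed as 1 minus a power: the negative logarithm of 1 minus p was a whole multiple, within 0.02, of 1 unit per category and library for 100% of the values below 1000 units. That unit is the share of transcript positions in the category, and the multiple is the rank of the alignment among those of its small RNA. The rank agreed within 1, or within a slightly wider margin at high ranks, between the libraries for 721 of 721 shared records that could be compared. The number of supported records expected from random placement was taken, after the data were seen, as the density of each category times the ranks that p at most 0.05 admits, summed over categories 0 to 2 and the 878 names. In the shared range it was scaled by the 20.7% of XZ153 records there. It is an upper figure for pairs and families, because similar names and isoforms fall on the same sites. For records it is an expected number and not a limit. For counts by isoform, listed target sequences of 1 gene with 14 bases in common were taken as 1 site, also chosen after the data were seen. In simulated lists the unit was recovered in 20 of 20 cases, and 0 of 20 lists of random p-values were called whole multiples.

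Shares have exact Clopper-Pearson 95% intervals, count ratios exact conditional intervals and single counts exact Poisson intervals. They cover counting error only, because PCR copies and isoforms are not independent molecules. With 1 library per cultivar no test between cultivars was made and no difference has a replicate check. The list of 31 conserved families and the rule for the sites named were fixed before the data were examined. The rule took, for each family, the site with the lowest p-value in either library, since reads were used for ZD9 only, and the 5 category 0 sites with most reads (ZD9) or lowest p-value (XZ153) among sites listed in that library alone. The rule's parts on annotated targets, on potassium transport genes and on read ratios could not be applied: of the genes in both lists, 0 matched an ID in the reference gene table (MorexV3), and the files do not pair IDs with gene names. Sites were merged by gene and restricted to the shared range in a second version of the rule, chosen after the data were seen. Alternatives covered the category, Allen score, p-value, read minimum, unit of counting and definition of a shared site. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.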

Results

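Cleavage sites were listed for 2 degradome libraries of barley shoots, 1 from ZD9 and 1 from XZ153, in a series on microRNAs under low potassium in Tibetan wild and cultivated barley. The XZ153 list held 40424 records on 21111 transcripts of 9317 genes for 869 small RNA names. The ZD9 list held 17485 records, of which 15544 had values, on 7113 transcripts of 2430 genes for 784 names. Raw reads in ZD9 summed to 34935 over the list, and 66.2% of its sites held a single read. The depth of either library is unknown.

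The first question was which microRNA families have supported cleavage sites in each cultivar. Sites of miR160, miR172, miR166, miR169, miR393 and miR1432 were supported in both libraries on the same genes, as was a site of a MIR156 hairpin arm. These families are textbook regulators: miR160 of auxin response factors, miR172 of AP2-like factors, miR166 of class III HD-ZIP factors, miR169 of NF-YA subunits and miR393 of auxin receptors. In XZ153, whose list covers all transcript IDs, 22 of the 31 conserved families had a supported site, with 181 records on 76 family and gene pairs (exact 95% interval 59.9 to 95.1). The p-values are unadjusted, and random placement at the library's category densities gives an expected 46.4 records for the names of these families. It also gives a supported site to up to 19.9 of the 31 families, so the number of families says little and a single supported pair is weak evidence on its own. Over all names XZ153 had 139 supported pairs (116.9 to 164.1), where random placement gives an expected 135 records. It had 273 supported records, in which isoforms repeat sites. In the ID range that both lists cover, 11 families had a supported site in ZD9, on 13 pairs, and 10 in XZ153, on 18 pairs. Random placement gives up to 7.61 and 7.67 families there, and an expected 9.49 and 9.59 records. The supported records there numbered 83 and 34, in which isoforms repeat sites. Under mature microRNA names alone the shared range had 9 families on 11 pairs in ZD9 and 9 on 14 in XZ153. There random placement gives up to 5.39 and 5.44 families, and an expected 6.35 and 6.42 records. The whole XZ153 list had 19 families on 63 pairs under these names, where random placement gives up to 16.2 families and an expected 31.1 records. Records of any quality existed for 29 of the 31 families in each library, with miR529 and miR403 absent from both lists, so the presence of a record separates few families.

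The strongest site in ZD9 by raw reads was that of miR160 on HORVU1Hr1G041770. Its 3 listed isoforms held 346, 337 and 334 raw reads, the 3 highest values of the ZD9 list, and all 3 were category 0 in both libraries. At position 2893 of isoform 6 the deposited p-value was 0.000675 in ZD9 and 0.000379 in XZ153. The miR172 site on HORVU1Hr1G011800 was category 0 on 27 of 27 isoforms in ZD9, with 5 to 19 reads. In XZ153 the site was listed on 21 of these isoforms, 6 of them in category 0, 1 in category 1 and 14 in category 4. At position 1737 of isoform 26 the site CUGCAGCAUCAUCAGGAUUCU had a p-value of 0.000135 in ZD9 and was not listed in XZ153. The miR169 site on HORVU2Hr1G032130 was category 0 on 16 of 20 isoforms in ZD9 and on 4 of the 12 listed in XZ153. The miR166 site on HORVU1Hr1G041790 was category 0 on 12 of 14 isoforms in ZD9 and on 1 of the 6 listed in XZ153. The other genes did not all go this way. The miR166 site on HORVU1Hr1G061830 was category 2 on 4 of 4 isoforms in both libraries, and the miR1432 site on HORVU0Hr1G005300 was category 0 on 1 of 10 isoforms in ZD9 and on 1 of 4 in XZ153. The MIR156 site was category 0 on 4 of 5 and 1 of 3, and the miR393 site on 0 of 4 and 0 of 1. These counts take every isoform listed at the site in either library, at any category, for genes supported in both libraries. Isoforms of 1 gene repeat the same cut, so the counts are not independent measurements. In XZ153 the miR172 cut ranged from category 0 to category 4 over isoforms, so the category of 1 isoform does not stand for the whole cut. The larger number of covered positions in ZD9 was not adjusted for.

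**Figure D1:**
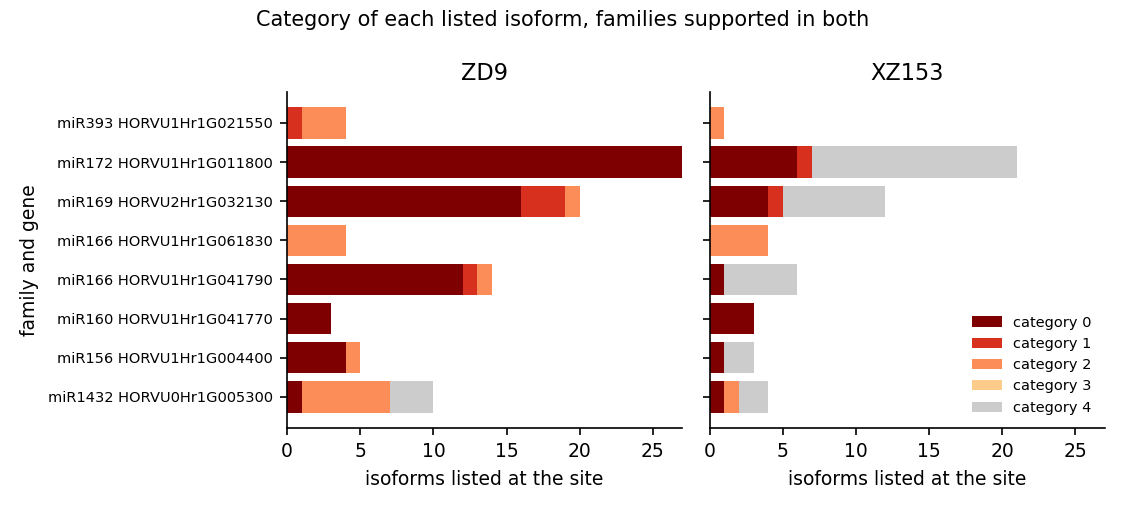
Best category of each isoform listed at the site, whether supported or not, for conserved families and genes with support in both libraries; bar length is the number of isoforms listed, colour the category, left ZD9 and right XZ153. The miR160 site is category 0 on 3 of 3 isoforms in both libraries, while 14 of the 21 isoforms listed for the miR172 site in XZ153 are category 4.

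Most family sites with the lowest p-values lay on transcripts beyond the end of the ZD9 list. The rule named a site for 29 families, 22 of them after the shared range. Of all XZ153 records 79.3% lay there too, so this number is no trait of the named sites. Sites of miR160 on HORVU2Hr1G125740, miR396 on HORVU2Hr1G094470, miR171 on HORVU6Hr1G063650 and miR1432 on HORVU5Hr1G111520 were category 0 in XZ153 with a p-value of 7.58e-05, the lowest that category allows there. The miR396 family regulates growth-regulating factors and miR171 GRAS-domain factors. Sites of miR164, miR169 and miR395 also passed, at 0.000679, 0.000455 and 0.000985. Of the 29 named sites 19 were supported and 10 were not. Among the latter were the best sites of miR159, miR168, miR390, miR394, miR528 and miR162, with p-values from 0.0607 for miR394 to 0.166 for miR528. The miR159 site was under a hairpin-arm name, and those of miR168, miR390, miR528 and miR162 under 3p names. None of these families had a supported site under any name in either list. The best sites of miR156, miR319, miR408 and miR2118 had p-values of 0.000951, 0.0043, 0.00858 and 0.00858 but lay in categories 3 or 4, where the position is weak on its transcript. The miR2118 site was under a hairpin-arm name. The families miR156, miR319, miR408 and miR2118 had other sites that were supported. For miR319 these were under hairpin-arm names alone, with deposited p-values of 0.0457 and 0.04995, close to the limit. Of the 12 families supported in XZ153 but not in ZD9, 10 were supported only on transcripts after the shared range, where most XZ153 records lie. Within the shared range 8 families were supported in both libraries, 3 in ZD9 only and 2 in XZ153 only.

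The second question was how the cultivars differ. In the shared range ZD9 had 15544 records and XZ153 8350, a ratio of 1.86 (95% interval 1.81 to 1.91). The whole lists give the opposite direction, 0.385, because the ZD9 list stops early. Category 0 records numbered 264 in ZD9 and 117 in XZ153, a ratio of 2.26 (1.81 to 2.83). Supported pairs of family and gene numbered 24 in ZD9 (exact 95% interval 15.4 to 35.7) and 36 in XZ153 (25.2 to 49.8), with 12 in both. Random placement over all names gives an expected 27.6 and 27.9 records there, an upper figure for pairs that both intervals include. The supported records there numbered 108 and 76, in which isoforms repeat sites. The pair counts alone therefore do not tell whether support exceeds random placement. The order of the pair counts turned when the same alignment rank, at most 100, was required in both libraries in place of the p-value. That gave 33 pairs in ZD9, 21 in XZ153 and 13 in both. A p-value of 0.05 admits category 0 alignments to rank 380 in ZD9 and to rank 676 in XZ153, which keeps the random figures nearly equal. A fixed rank instead admits more random records in the denser library. Positions of categories 0, 1 and 2 were 1.78, 2.01 and 3.05 times as dense in ZD9, so the turn by rank can arise from density alone. With the p-value kept, the order also turned at an Allen score of at most 2.5, with 8 pairs in ZD9 and 6 in XZ153. XZ153 stayed higher at a p-value of at most 0.01, for category 0 alone and under mature names. The number of supported pairs therefore gives no direction between the cultivars.

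**Figure D2:**
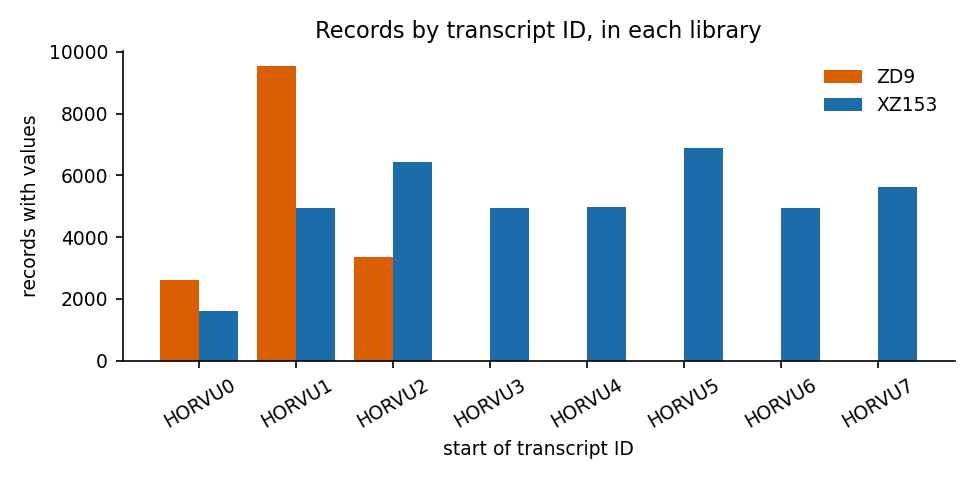
Number of records with values (vertical axis) by the start of the transcript ID (horizontal axis) in ZD9 and XZ153. ZD9 has 9559 records in HORVU1 against 4958 in XZ153 and none from HORVU3 on.

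Among category 0 sites listed in ZD9 alone, the highest read counts belonged to miR398, a family known for targets in copper and superoxide metabolism. Its site on HORVU2Hr1G021110 held 49 reads at position 290 of isoform 1 and 41 reads at position 115 of isoform 3, with p-values of 0.0381 and 0.0362 and an Allen score of 4.5. The XZ153 list has 7 records on that gene, none at this site, and no supported miR398 site. The next sites of the rule, for MIR5082 with 35 and 23 reads, had a p-value of 1, and the last was the miR172 site at position 1737 described above. The last is not a site of ZD9 alone, since XZ153 lists it on 21 of the 27 isoforms. With isoforms merged it drops out, and miR398 and MIR5082 are followed by miR1120 with 17 reads and MIR5049d with 14, at p-values of 0.125 and 0.321. In XZ153 the rule named category 0 sites of miR396, miR160 and miR1432, all after the shared range. These tied with others: 7 sites share the lowest p-value, and the order of IDs decided which 5 were named. Within the range, with isoforms merged, the lowest p-values were 0.000227 for miR5168 on HORVU0Hr1G010250 and 0.00416 for miR172 on HORVU1Hr1G024190. The first is not a site of XZ153 alone. It lies at position 471 of isoform 6, and the same position and sequence on isoform 3 is listed under miR166, in category 0 in XZ153 with a p-value of 0.000379 and with 1 read in ZD9, so both names mark 1 cut. None of these differences has a replicate check.

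The third question was how far both lists share sites. Over all records 4783 combinations of small RNA and site were in both lists, but 1941 of these are ZD9 records without values. In the shared range the number was 2842, which is 18.3% of the ZD9 and 34.0% of the XZ153 records there. Over all sites recurrence rose with the reads in ZD9. Of sites with 1 read 10.2% (9.66 to 10.8) were also listed in XZ153, of those with 3 to 5 reads 38.3% (36.0 to 40.5), and of the 115 sites with more than 20 reads 93.9% (87.9 to 97.5). Isoforms repeat sites, and by gene all sites with more than 20 reads were listed in XZ153 for 30 of 35 genes, or 85.7% (69.7 to 95.2). Among supported sites recurrence did not rise throughout: 16.7% (3.58 to 41.4) at 2 reads, 51.6% at 3 to 5, 80.6% at 6 to 10, 69.6% (47.1 to 86.8) at 11 to 20 and 60% (14.7 to 94.7), or 3 of 5, above 20. Those 5 are isoforms of 2 genes, and the ones not listed are the miR398 site named above. The category was the same for 1428 of the 2842 shared records, or 50.2%. Of the 76 shared records in category 0 in ZD9, 18 were category 0 in XZ153 and 36 were category 4. Isoforms repeat sites here too, and categories were not compared by gene. In XZ153 the miR172 site on HORVU1Hr1G011800, the miR169 site on HORVU2Hr1G032130 and the miR166 site on HORVU1Hr1G041790 had 14, 7 and 5 isoforms in category 4. Read ratios between the cultivars were not analysed here.

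**Figure D3:**
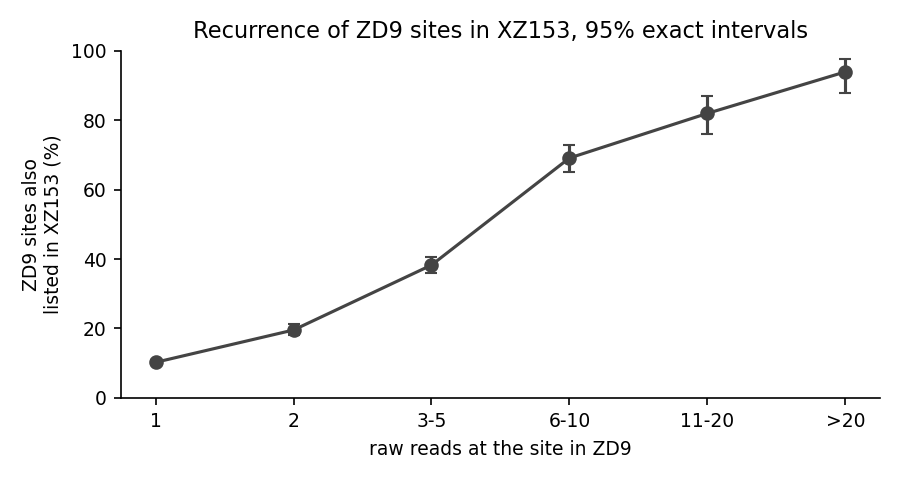
Percentage of ZD9 sites also listed in XZ153 (vertical axis) by raw reads at the site in ZD9 (horizontal axis), with exact 95% intervals. The share rises from 10.2% at 1 read to 93.9% above 20 reads.

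Category 0 made up 1.70% of ZD9 records (1.501 to 1.91) and 1.40% of XZ153 records (1.16 to 1.68) in the shared range, with 1.49% (1.37 to 1.61) in the whole XZ153 list. All transcript positions with reads, taken from the units of the p-values, held 1.11% and 1.35% category 0. Well-paired sites had higher category 0 shares than poorly paired ones. A family and gene pair can hold several records, so its share is compared between Allen scores and not with the share of positions. At an Allen score of at most 2.5, a category 0 site was found for 7 of 79 family and gene pairs in ZD9, or 8.86% (3.64 to 17.4), and for 5 of 52 in XZ153 in the shared range, or 9.62% (3.196 to 21.03). The whole XZ153 list gave 33 of 219, or 15.1% (10.6 to 20.5). Above a score of 10 the shares in the shared range were 1.73% and 1.89%. By record the well-paired shares were 18.6% (13.7 to 24.3) in ZD9 and 7.91% (4.02 to 13.7) in XZ153 in that range, where isoforms of the same gene count repeatedly. By record, miR169 and miR172 supplied 16 and 15 of the 41 category 0 records at that score in ZD9, and miR160, miR169 and miR396 supplied 22, 13 and 11 of 69 in the whole XZ153 list. The miR1439, miR5049 and miR1862 families had many well-paired records in that list, 50, 46 and 48, with 3, 2 and 1 in category 0.

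**Figure D4:**
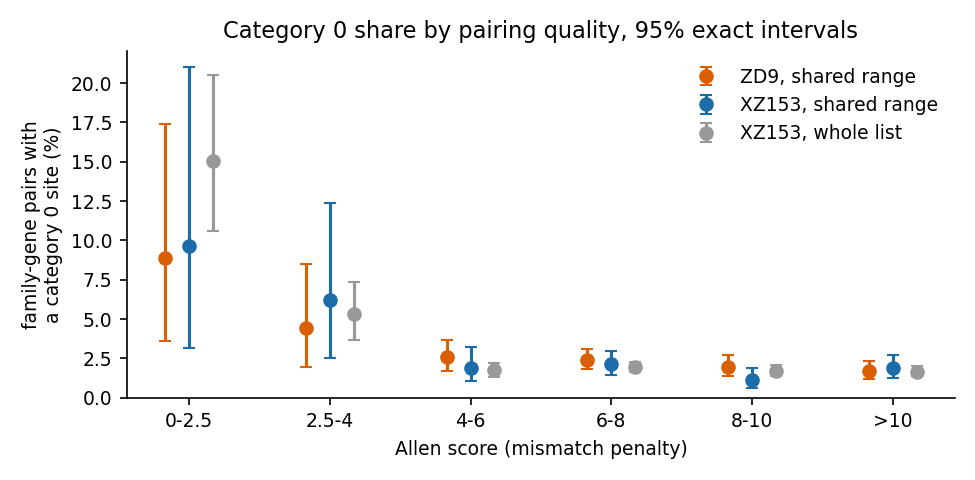
Percentage of family and gene pairs with a category 0 site (vertical axis) by Allen score, a mismatch penalty (horizontal axis), in ZD9 and XZ153 over the shared range and in the whole XZ153 list (grey), with exact 95% intervals. At a score of at most 2.5 the shares are 8.86% in ZD9 and 9.62% in XZ153 in the shared range and 15.1% in the whole XZ153 list, against 1.73%, 1.89% and 1.67% above 10.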

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

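All tests in this part were chosen after the results were seen. The ZD9 list closes with 1941 records that name a site and a small RNA but hold no values. They entered the counts of 17485 listed and 4783 shared records, the alternatives of these by name or by family and gene, and the count of families with any record, but no category, p-value or shared-range result. All of them, 100%, were found in the XZ153 list as 1 run with 0 breaks, against 18.7% of the ZD9 records with values. A ZD9 list that holds part of the ZD9 sites and ends with a stretch taken from the other list would show this. The deposited normalised values scale to 34944 reads, 9 above the 34935 listed, so they were computed on a list about this short. A list without ZD9 reads on later transcripts would scale the same way. At which step the stretch without values was added is not known. An absence of ZD9 reads on later transcripts is argued against by the density of covered positions in the p-values, which was 2.17 times that of XZ153, where such an absence needs a ratio below 1. That reading rests on densities computed over all transcripts in both libraries.

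Positions with reads made up 1.22% of transcript positions in ZD9 and 0.562% in XZ153. A few genes with many listed sites do not account for the denser ZD9 degradome, since 70.4% (68.6 to 72.1) of the genes with unequal record numbers in the shared range had more in ZD9, where a few genes would leave at most 50%. More reads in the ZD9 library stay open. Categories 1, 2 and 3, which hold at least 2 reads, were 2.01, 3.05 and 3.08 times as dense in ZD9, above the 1.95 of single-read category 4. Category 0 was below it at 1.78. That category is only the highest position of each transcript, so the number of transcripts limits it and its ratio cannot decide the question. More RNA decay intermediates in ZD9 shoots would also give the overall ratio of 2.17 and cannot be told apart from depth, because neither library's total is known.

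The miR398 site on HORVU2Hr1G021110, with 49 and 41 reads in ZD9, was not listed in XZ153. Sampling of few reads stays open: all ZD9 sites with more than 20 reads were listed in XZ153 for 85.7% of 35 genes (69.7 to 95.2), and the site was singled out as the extreme of 7 missing sites on 5 genes. Of the 5 supported sites above 20 reads, isoforms of 2 genes, 3 were listed, all of the miR160 site. The 2 not listed are the miR398 site itself, so this share adds no evidence. Of the lines left out of the XZ153 list, 0 lie at the place of this gene. A difference between the cultivars, in the microRNA, the transcript or its sequence at the site, stays open too: the 7 XZ153 records on the gene at other positions show reads from it, and 1 library per cultivar cannot separate cultivar from library.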

How the results depend on the processing

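Of 71 alternatives, 21 left a count within 1.5 times, or a share or ratio within its 95% interval, 49 moved it and 1 turned it. Those on the shared range, mature names, combined support and record ratio were chosen after seeing the data. The ratio of ZD9 to XZ153 records in the shared range, 1.86, turned to 0.385 over the whole lists, because the ZD9 list stops early. It was 2.27 at category 0 to 2, 1.59 at an Allen score of at most 2.5, 1.92 under mature names and 1.49 by family and gene.

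ZD9 records fell from 17485 to 3618 at category 0 to 2, 221 at the stricter Allen score, 142 at p at most 0.05, 108 with category and p combined, 4788 under mature names, 1177 at 5 or more reads and 8331 by family and gene. XZ153 records fell from 40424 to 7722, 500, 415, 273, 10356 and, by family and gene, 22578, with 8350 in the shared range. Shared records fell from 4783 to 523, 63, 50, 27 and, under mature names, 1322, with 2842 in the shared range, which leaves out the 1941 ZD9 records without values. Positions within 2 nt gave 4783 again.

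The category 0 share rose in ZD9 from 1.70% to 18.6% at the stricter Allen score, 48.6% at p at most 0.05, 2.498% under mature names, 2.42% by family and gene and 10.03% at 5 or more reads. In XZ153 it rose from 1.49% to 13.8%, 38.3%, 2.49% and 2.13%. A category enters the p-value, so the rise with p follows from its construction. Conserved families numbered 29 in both, and in ZD9 9 at the stricter Allen score and 11 at p at most 0.05, alone or combined with category. In XZ153 they were 14 at the stricter Allen score.

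Supported pairs in ZD9, XZ153 and both were 24, 36 and 12. They were 12, 15 and 9 at p at most 0.01, 11, 19 and 6 for category 0, 8, 6 and 5 at the stricter Allen score, 14, 15 and 7 under mature names, and 33, 21 and 13 by alignment rank. XZ153 was higher under 3 of these alternatives and lower under 2. The rank limit by its construction favours ZD9, the denser library.

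The alternatives on depth, read ratios, normalization and pseudocount, and the read minimum in XZ153 and for shared records, were not run, since reads were used for ZD9 only. No paired analysis was possible because each cultivar has 1 library.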

Other observations

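Small RNA names were those of mature microRNAs, those of hairpin arms and a few that start with PC. These counts were chosen after seeing the data. Among the 100 best alignments of each of 332 mature names, XZ153 had 117 category 0 records on 35 genes, where random placement at the library's category 0 density gives 2.52. For 503 hairpin-arm names it had 7 records on 7 genes, where random placement gives 3.81 (exact 95% interval of the observed count 2.81 to 14.4). The 34 PC names had 0. In ZD9, with the expectation scaled by the 20.7% of XZ153 records in the shared range, the mature names had 60 records on 5 genes where random placement gives 0.822. The ZD9 hairpin-arm names had 0 where it gives 1.29, and a count of 0 allows up to 3.69, so this is no departure from chance. Among the 1000 best alignments the excess of mature names was smaller. XZ153 had 132 records on 48 genes where random placement gives 25.2, and ZD9 68 records on 12 genes where it gives 8.22. Hairpin-arm names were at the random level there, with 34 against 38.1 in XZ153 and 13 against 12.9 in ZD9. Hairpin-arm names supplied 29377 of the 40424 XZ153 records.

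The most frequent name in both lists was that of MIR10422, with the sequence UGUUGUUGGUGGUGGUGG. It had 407 records in ZD9 and 1292 in XZ153, of which 0 were supported in either library. The next names, for MIR169m and MIR169g hairpin arms, had 400 and 385 records in ZD9 and 1251 and 1200 in XZ153, again with 0 supported.

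Sites of MIR5368 formed ladders of neighbouring positions. On isoform 2 of HORVU0Hr1G025120, XZ153 had 18 records between positions 329 and 474, 11 of them directly next to the one before, and ZD9 had 14 between 379 and 447, with 8 directly adjacent. No Allen score of MIR5368 on this gene was above 2 and no record of isoform 2 was category 0 in either library. On the whole gene XZ153 had 1 category 0 record, with a p-value of 0.000227, and ZD9 had 0. The pairs on this gene and on HORVU0Hr1G036450 were among the 12 supported in both libraries.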
